A study of Mus musculus with 4 samples.

How the data were processed

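Chromatin accessibility was measured with ATAC-seq, in which a transposase cuts open DNA and inserts sequencing adapters, in endothelial cells sorted by FACS from mouse retina (C57BL/6, labelled P16). Per the labels' protocols, 2000 sorted cells were used for each library. There were 4 libraries: 2 from control mice and 2 from mice whose genotype is given as Zeb1 knockdown, with CKO in the sample titles. The groups and the replicate numbers were taken from those titles. Nothing in the labels states whether the 2 libraries of a group came from separate animals or pools, so the spread between libraries may be technical. Only the permutation test compares libraries. The other p-values take genes or regions as units and measure no spread between libraries or animals.

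The deposited files are 4 lists of broad peaks, 1 per library and not pooled, on mm10. Per the submitters' processing notes, the tools were Trimmomatic 0.36, Bowtie2 2.3.2, Picard 2.9.2, SAMtools 1.3, MACS2 2.1.1 and bedtools 2.26.0. The notes as used here give no roles, order or settings, so whether reads were shifted for the transposase offset is not given in the sources used here. In the deposited lists, each peak has a fold enrichment (a ratio over its own library's background), a −log10 p, a −log10 q, and a score that is 10 times the −log10 q, truncated to a whole number and limited to 1000. Every deposited −log10 q was above 1, so each list ends at a q of 0.1. The authors' peak names are numbered, and 64 to 79 numbers per list, 0.321% to 1.03% of the highest number, are missing from the filtered lists. The filter itself is not given in the sources used here. Because each list was called on its own library, fold enrichment and −log10 q were used only to rank and filter peaks within a list, never to compare libraries. Read depth is unknown, so the absence of a peak cannot be told from too few reads.

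Peaks on the 19 autosomes and X were merged across the 4 libraries where they overlapped or touched. A library held a region if 1 of its peaks overlapped it by at least 1 bp. A region held by both knockdown libraries and neither control is called knockdown-only, and the reverse control-only. With 2 libraries against 2, an exact permutation test has 6 arrangements and a two-sided p that cannot go below 0.333, so no region or gene was tested on its own. Counts of regions were set beside the same counts for the other splits of the libraries. The design also fixed a co-detection ratio, which is free of library sensitivity only if sensitivity acts alike on all regions, and this did not hold for control replicate 1. Among regions held by exactly 2 libraries, it divides the product of the 2 same-group counts by the product for another pairing. Its 95% interval comes from 1000 resamples of the chromosomes and describes these 4 libraries, not the conditions.

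Gene coordinates came from an NCBI RefSeq gene table on GRCm38.p6, whose chromosomes are those of mm10. The table gives the 2 ends of each gene but no strand, exons or transcript starts. The planned promoter windows around transcription starts were therefore replaced by windows of 1 kb on each side of either gene end, called gene ends here, and a gene end can be the start or the far end of a gene. The planned split into exons and introns was reduced to gene end, gene body and between genes. No genome sequence was used here, and the planned search for transcription factor motifs, among them the E2-box bound by Zeb1, was not run. Protein-coding genes and the listed microRNA genes on the same chromosomes made up 21636 genes.

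Before the data were examined, 18 gene lists were fixed, 11 for endothelial functions and pathways and 7 for other cell types of the retina. Of their 414 genes, 413 were in the gene table. For each list, a two-sided Fisher's exact test compared the share of knockdown-only (and of control-only) members with that of all other genes holding a gene-end peak in at least 1 library, with Benjamini-Hochberg adjustment over the 36 tests. Genes are not independent replicates, and these tests describe the 4 libraries. Locus windows added 10 kb on each side of the gene body. The naming rule, fixed in advance, took Zeb1, up to 6 members per list and direction in order of the weaker of the 2 peak ranks, and the gene with an end nearest to each of the 10 best-ranked regions per direction, within 50 kb. Another 4 lists, a comparison of control replicate 2 with knockdown replicate 1, and some tests of explanations were chosen after seeing the data. Results for some single genes are not reported here.

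Alternatives were a −log10 q of at least 3 (q of 0.001), the 7608 strongest peaks of each library, each library left out in turn, regions of which at least 50% is covered, peaks within 1 kb merged, all sequences including Y, windows of 3 kb, other backgrounds for the list tests, and the replicate number as a block. Functions were tested on simulated data at the real list lengths. In the simulation of the knockdown against control comparison with 56432 sites, 200 of 200 planted knockdown-only sites were recovered. With no planted effect, the co-detection ratios came to 0.957 against same-number and 0.958 against crossed pairs, and 0 lists passed. Planted sites were set directly to the knockdown-only pattern, and the null followed the sensitivity model that control replicate 1 breaks. The simulation therefore checks the functions, not how the ratios or list tests behave on these libraries. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.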

Results

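Accessible chromatin of sorted retinal endothelial cells was compared between control mice and mice with Zeb1 knockdown, with 2 libraries in each group. Zeb1 is a zinc-finger transcription factor known as a repressor of epithelial genes. The control libraries held 7608 and 13672 peaks and the knockdown libraries 13689 and 19886 peaks, for replicates 1 and 2 respectively. The group means were 10640 ± 4288 (SD, n = 2) and 16788 ± 4382 peaks (SD, n = 2), a ratio of 1.58. The two-sided exact permutation test gave p = 0.333, the smallest value that 2 against 2 allows. The lists covered 3481 and 5669 kb in the controls and 7079 and 9165 kb in the knockdown libraries. Median peak width lay between 343 and 445 bp. The authors' median fold enrichment per peak lay between 3.91 in control replicate 1 and 5.19 in control replicate 2. Read depth is not known from these lists.

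At Zeb1 itself (chromosome 18, 5591327 to 5775468, mm10), a peak overlapped the low-coordinate end of the gene in control replicate 2 and in both knockdown libraries, and none was listed in control replicate 1. In knockdown replicate 1 this peak ran from 5591166 to 5591965. Within the gene body, 1 further peak was listed in knockdown replicate 1 and 2 in knockdown replicate 2. Peak lists do not show whether the gene was deleted or transcribed, so they do not check the genotype labels.

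Epithelial genes that Zeb1 is known to repress held peaks at their gene ends in the knockdown libraries and mostly none there in the controls. Of the 32 listed genes, 2 and 3 had a gene-end peak in the control libraries, against 17 and 20 in the knockdown libraries. In all, 13 members were knockdown-only, 0 were control-only, and 1 (Pard6b, a cell polarity gene) was held by all 4 libraries. The 13 made up 65% of the 20 members with any gene-end peak, against 7.71% of the other genes (two-sided Fisher's exact test, odds ratio 22.2, adjusted p = 6.22e-09). Of the 10499 genes with a gene-end peak, 4529 were held by all 4 libraries and so could not be knockdown-only. Among only the genes held by exactly 2 libraries, the difference was weaker but still passed (Fisher's exact test, 13 members knockdown-only, adjusted p = 0.00854). Over the gene body and 10 kb on each side, 11 and 17 of the 32 had a peak in the controls and 28 and 31 in the knockdown libraries, and 11 were knockdown-only (Fisher's exact test, odds ratio 8.67, adjusted p = 3.59e-05). Of these 11, Mir200a, Mir200b and Mir429 were called from the same peak in each knockdown library, and the test counts them separately. None of the other splits of the 4 libraries gave any such member at gene ends: 0 members were held by both libraries of one replicate number, or of one crossed pair, and by neither of the others. Those patterns were uncommon over all 10499 genes with a gene-end peak, 632 for replicate 2 and 17 for replicate 1. A count of 0 in 20 members is therefore not unusual (Fisher's exact test, p = 0.630 for replicate 2).

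The best-ranked of these genes were the tight junction claudins Cldn3 and Cldn4, followed by the protease inhibitor Spint2, the adhesion molecule Epcam, the polarity scaffold Patj and the epithelial splicing regulator Esrp1. The Cldn3 peaks, at chromosome 5 from 134985699 to 134986355 after merging, ranked within the top 7.36% of peaks in both knockdown libraries. The remaining 7 lay outside the naming rule and were picked after their values were seen. They were Cdh1 (E-cadherin), Cldn7, Marveld3, Spint1, Grhl2, Crb3 and St14. At Cdh1 (chromosome 8, 106603350 to 106670247), the knockdown libraries held 3 and 5 peaks in the gene and its 10 kb flanks, and the controls held 0 each. Many of these peaks were weak: the weaker St14 peak stood at percentile 95.8 from the top of its list.

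The epithelial difference was present within each replicate number, 2 against 17 members for number 1 and 3 against 20 for number 2. Control replicate 2 and knockdown replicate 1 had lists of nearly equal length, 13672 and 13689 peaks. Between them, 14 epithelial members had a gene-end peak only in the knockdown library and 0 only in the control library (exact two-sided sign test, adjusted p = 0.0022 over the 18 lists). Of these 14, 13 are the knockdown-only members themselves, so this test is not separate evidence. Its null was an even split, while over all genes 1164 were held only by the knockdown library and 941 only by the control library. With a −log10 q of at least 3, 7 members were knockdown-only, 5 of them among the 13 (Fisher's exact test, odds ratio 6.17, adjusted p = 0.0288). When only the 7608 strongest peaks of each library were kept, 3 members remained knockdown-only and the call was lost (Fisher's exact test, odds ratio 6.91, adjusted p = 0.549). Without control replicate 2, 15 members were knockdown-only, with an odds ratio of 5.69 (Fisher's exact test, adjusted p = 0.00842).

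A region near the microRNA cluster Mir200b, Mir200a and Mir429, whose members are known to target Zeb1 messenger RNA, was knockdown-only and ranked in place 4 of such regions. It spanned chromosome 4 from 156059344 to 156060145, 3594 bp from Mir200b, within the top 5.80% of peaks in both knockdown libraries and absent from both control lists. The second cluster, Mir200c and Mir141 on chromosome 6, had a peak 5325 to 5954 bp away in all 4 libraries.

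**Figure D1:**
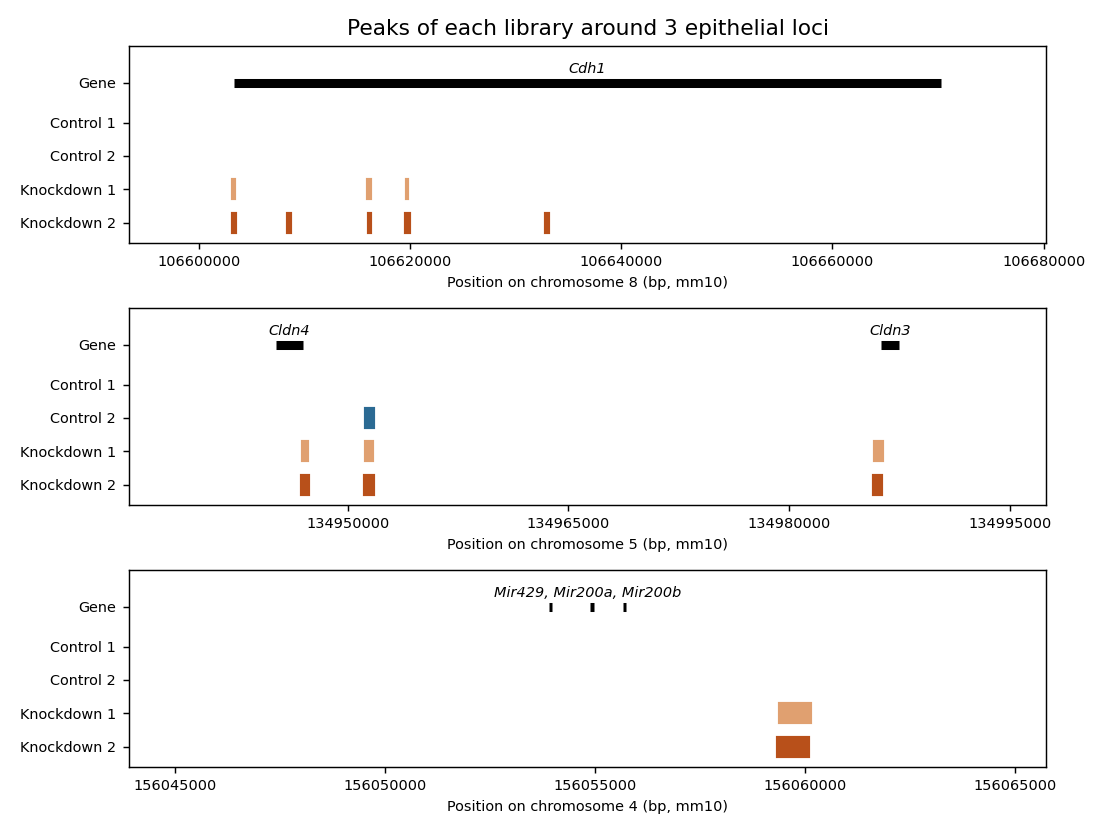
Peaks of the 4 libraries (coloured boxes, 1 row per library) along chromosome position in bp on mm10, with gene extents in black, each panel reaching 10 kb beyond the genes. Only peaks within 10 kb of a drawn gene are shown, so the middle stretch between Cldn4 and Cldn3 is blank by construction. Cdh1, Cldn3 and the Mir200b cluster have peaks in the knockdown rows only, and a peak 4192 to 4271 bp from Cldn4 is also in control replicate 2.

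Genes of sprouting and tip cells, the leading cells of a growing vessel, held more peaks in the knockdown libraries, but the call depended on the window. At gene ends, 4 and 7 of 24 members had a peak in the controls and 15 and 14 in the knockdown libraries. Knockdown-only gene ends were those of Adm, the vasoactive peptide adrenomedullin, and of the basement membrane collagens Col4a1 and Col4a2, which share 1 peak between them. These 3 of 18 did not pass (odds ratio 2.36, adjusted p = 1 by Fisher's exact test). Over the gene body and 10 kb on each side, 6 of 23 members with a peak were knockdown-only, namely Adm, Apln, Esm1, Kcne3, Lamb1 and Plaur (26.1% against 6.00% of other genes, adjusted p = 0.0353 by Fisher's exact test). In the comparison of equally long lists, 8 members had a gene-end peak only in knockdown replicate 1 and 0 only in control replicate 2 (exact sign test, adjusted p = 0.0469), and 3 of the 8 are the knockdown-only members. The null of this test was an even split, but over all genes 1164 were held only by knockdown replicate 1 and 941 only by control replicate 2. That background leans the same way and the p lies near the threshold, so no call is drawn from it.

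Among mesenchymal and TGF-beta genes, 5 of 15 members with a gene-end peak were knockdown-only, among them Cdh2 (N-cadherin), Tgfbr2, Col1a1 and Cdh11. This list did not pass (odds ratio 5.92, adjusted p = 0.0805 by Fisher's exact test). Over the gene body and 10 kb on each side, 2 of 24 members with a peak were knockdown-only, 8.33% against 6.03% of other genes. The odds ratio there was 1.42, and the list did not pass there either. Per library, 5 and 10 of 30 members had a gene-end peak in the controls and 15 in each knockdown library.

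Endothelial identity genes held peaks in both groups. At gene ends, 5 and 12 of 30 members had a peak in the controls and 12 and 16 in the knockdown libraries, and 14 had none in any library. Over gene body and flanks, 18 and 28 of 30 members had a peak in the control libraries and 29 and 30 in the knockdown libraries. Cdh5 (VE-cadherin), the receptor gene Tie1, Clec14a, Elk3 and Ushbp1 had a gene-end peak in all 4 libraries, and 2 members, Myct1 and Esam, were knockdown-only at a gene end. Of the 30 barrier and Wnt genes, 8 and 15 had a gene-end peak in the controls and 14 and 18 in the knockdown libraries. Cldn5, the main claudin of the endothelial barrier, the glucose transporter Slc2a1 and the Wnt receptor Fzd4 were among the 8 open in all 4, and Lrp6 was the single knockdown-only member.

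The Notch and arteriovenous list had 2 knockdown-only gene ends (Gja4 and Jag2), the cell cycle list 2 (Ccnb2 and Mcm6), and the inflammation and hypoxia lists 1 each (Nfkb1 and Hk2). The immediate early and dissociation stress list had 0, and 17 of its 22 members, among them Fos, Jun, Egr1 and Atf3, were open in all 4 libraries. Gene-end peaks in control 1, control 2, knockdown 1 and knockdown 2 were held by 7, 16, 17 and 19 of 26 Notch genes and by 10, 18, 19 and 22 of 26 cell cycle genes. For the 24 inflammation genes these counts were 5, 10, 10 and 11, for the 20 hypoxia genes 6, 13, 14 and 14, and for the 26 ribosomal genes 14, 22, 20 and 22. None of these lists, nor the endothelial and barrier lists, passed, with an adjusted p of 1 for each (Fisher's exact test). Across all 18 lists, 0 members were control-only at a gene end, and with 7 control-only genes in the genome this direction had almost nothing to test.

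None of the 7 marker lists of other retinal cells passed for genotype at gene ends (adjusted p = 1 for each, Fisher's exact test). The photoreceptor list followed the replicate number: 12 of 28 members had a gene-end peak in each replicate 2 library, against 3 in control replicate 1 and 4 in knockdown replicate 1. Of these, 7 members were held by both replicate 2 libraries and neither replicate 1 library (Fisher's exact test, odds ratio 15.8, adjusted p = 0.000118 over the 18 lists). Among them were the rod transducin gene Gnat1 and Guca1b, Pde6b, Pde6g, Prph2 and Rcvrn, picked after their values were seen. In the equally long lists, 8 members had a peak only in control replicate 2 and 0 only in knockdown replicate 1 (exact sign test, adjusted p = 0.0469), and 7 of the 8 are the 7 members with that pattern. The null was again an even split, and here the background of all genes leans the other way, to knockdown replicate 1. With the 7608 strongest peaks of each library, 1 member had the replicate 2 pattern (Fisher's exact test, p = 0.308). The epithelial, sprouting and mesenchymal lists had 0 members with this replicate 2 pattern. Over all genes with a gene-end peak, 632 of 10499 had it, so these counts of 0 are not unusual.

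Other inner retinal neurons had 1 knockdown-only gene end (Slc6a9), with 1 and 1 of 24 members open in the controls and 2 and 4 in the knockdown libraries. Knockdown-only gene ends numbered 0 for Muller glia and astrocytes, pericytes and smooth muscle, leukocytes, pigment epithelium and erythroid cells. Gene-end peaks per library, in the order control 1, control 2, knockdown 1 and knockdown 2, were 4, 6, 4 and 5 of 18 glial genes. They were 1, 2, 2 and 2 of 16 pericyte genes and 2, 1, 2 and 2 of 18 leukocyte genes. They were 2, 3, 2 and 3 of 12 pigment genes and 1 of 11 erythroid genes in every library.

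**Figure D2:**
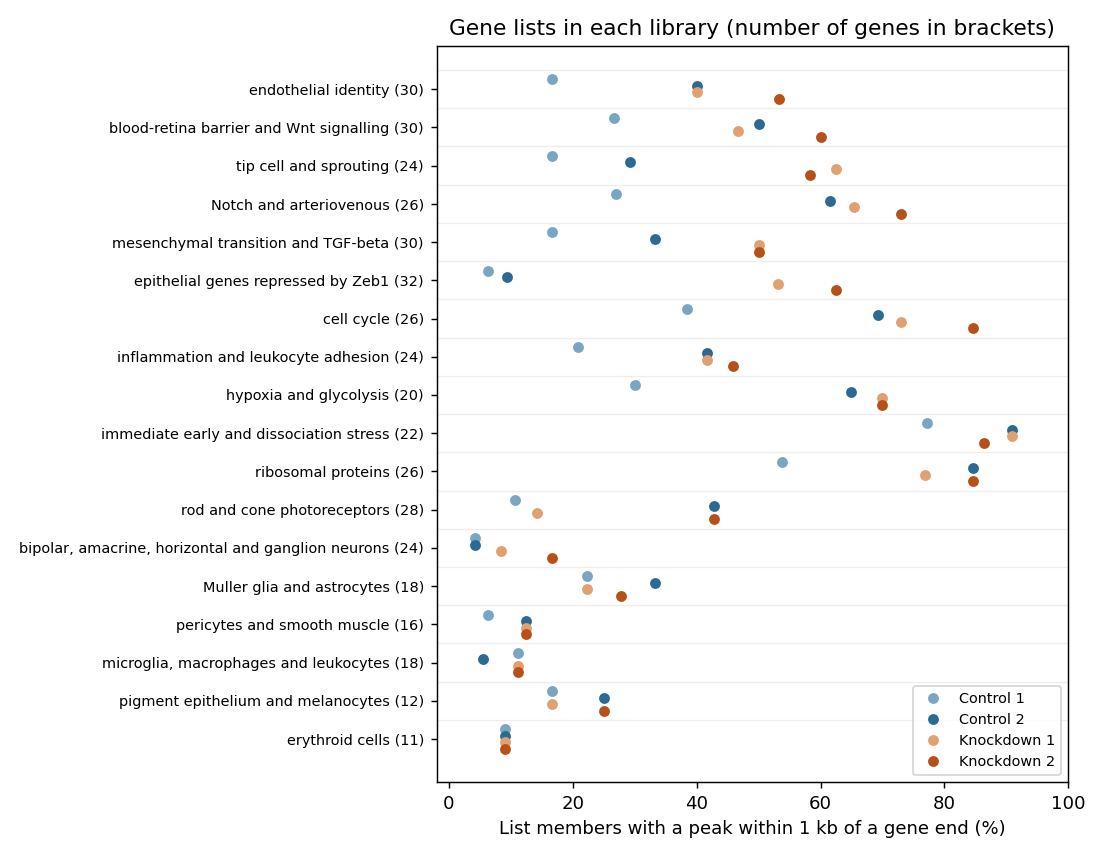
Share of each list's genes (%, horizontal axis) with a peak within 1 kb of a gene end, 1 dot per library, for the 18 lists fixed in advance (vertical axis, number of genes in brackets). The epithelial list separates the knockdown dots (17 and 20 of 32 genes) from the control dots (2 and 3), and the photoreceptor list separates the replicate 2 dots (12 and 12 of 28) from the replicate 1 dots (3 and 4).

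Genome-wide, the 4 lists merged into 25263 regions, of which 5120 (20.3%) were held by all 4 libraries and 10595 by a single library. Knockdown-only regions numbered 2555 (10.1%) and control-only regions 40 (0.158%). For gene ends the counts were 821 and 7 genes, out of 10499 with a peak in any library. The 7 control-only genes were Ankrd26, B4galt4, Cfap206, Dus3l, Ech1, Osgepl1 and Pycrl.

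Both counts depended on single libraries. With 1 library of a group left out, a region held by the remaining library alone counts for that group, while the other group still needs a peak in both. The counts of the 2 directions are then unlike. Without control replicate 1, the shortest list, 2738 regions were knockdown-only and 1944 control-only, and for gene ends 900 and 266. In the full set, control replicate 2 alone held 1903 regions. Without control replicate 2 the region counts were 6749 and 1926 and the gene-end counts 3543 and 68. Without knockdown replicate 1 they were 8281 and 90 regions and 1755 and 16 gene ends, and without knockdown replicate 2 they were 3704 and 142 regions and 1068 and 50 gene ends. With the 7608 strongest peaks of each library, the counts were 791 and 210 regions. Between the equally long lists of knockdown replicate 1 and control replicate 2, 9655 regions were shared, 3997 were found only in the knockdown library and 3980 only in the control library, counts that lists of equal length hold close together. Of the 1884 regions held by control replicate 1 alone, 3.24% lay at a gene end, against 15.8% to 23.8% of the regions held by any other single library.

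**Figure D3:**
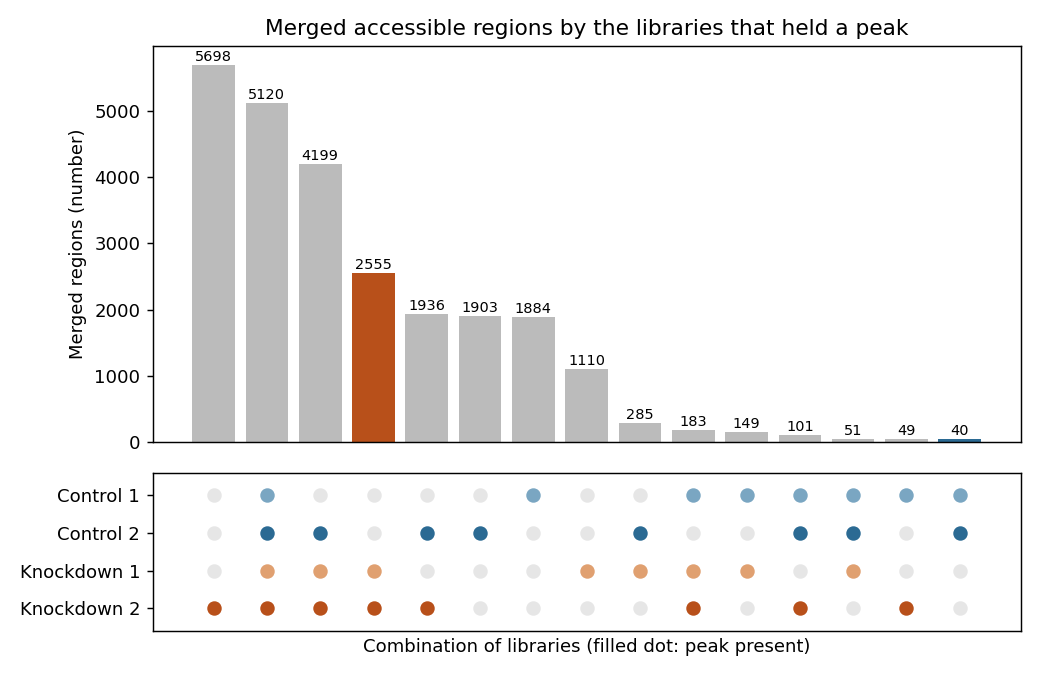
Number of merged regions (vertical axis) for each combination of libraries that held a peak, with filled dots below each bar naming the libraries. The 2555 knockdown-only regions are in orange and the 40 control-only regions in blue, and the 1936 regions held by the replicate 2 libraries alone form the second largest pair.

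Among regions held by exactly 2 libraries, sharing followed the replicate number as well as the genotype. Other splits gave 1936 regions for the replicate 2 libraries and 149 for the replicate 1 libraries, and the crossed pairs gave 285 and 49. The co-detection ratio of same-group over crossed pairs was 7.32 (95% interval 4.41 to 11.2), and that of same-group over same-number pairs was 0.354 (0.227 to 0.544). Among these regions, same-group libraries thereby shared more than crossed libraries and less than same-number libraries at these thresholds. Over all regions the order was not the same. Of the regions held by either library of a pair, both held 33.4% (control) and 56.2% (knockdown) in same-group pairs. Same-number pairs had 35.0% (replicate 1) and 51.3% (replicate 2). Control replicate 2 with knockdown replicate 1 had 54.8%, and the other crossed pair 24.8%. These shares also depend on list length. With a −log10 q of at least 3, the interval of the first ratio included 1 (2.48, 0.982 to 5.10). With equal lists, so did that of the second (0.899, 0.720 to 1.15).

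The 10 best-ranked knockdown-only regions included, besides those of Mir200b and Cldn3, regions nearest to Hrh2 (a histamine receptor, 1685 bp away), Man1a, Ifng, Shroom3 (an actin-binding regulator of epithelial cell shape), Nrde2 and Tspan14. The region near Shroom3 lay 40253 bp from the nearest gene end, at chromosome 5 from 92924862 to 92925506. The first 2, on X at 4899268 to 4899538 and on chromosome 6 at 46801912 to 46802142, had no gene end within 50 kb. The best-ranked control-only region, 112 bp from an end of Slc30a4 (a zinc transporter) at chromosome 2 from 122681345 to 122682324, was at percentile 46.1 in the weaker of its 2 lists. The next ones with a gene nearby were nearest to Osgepl1, Pdlim5, Sgip1, Myo16, Anks1 and Abcc4.

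Knockdown-only regions lay at gene ends in 29.9% of cases, in gene bodies in 38.8% and between genes in 31.3%. The control-only regions were at gene ends in 20% of cases, and regions held by all 4 libraries in 74.7%. The gene-end share of knockdown-only regions did not differ detectably from that of the other regions held by exactly 2 libraries, 30.8% (two-sided Fisher's exact test, odds ratio 0.960, p = 0.517), nor from that of control-only regions (odds ratio 1.71, p = 0.222). With other peak thresholds the share was lower than in the other regions: 34.4% against 52.5% with the 7608 strongest peaks of each library (odds ratio 0.474, p = 4.26e-16) and 39.1% against 43.0% with a −log10 q of at least 3 (odds ratio 0.850, p = 0.0149), both by Fisher's exact test. The direction changed with the overlap rule: where peaks had to cover 50% of a region, the odds ratio was 1.15 (Fisher's exact test, p = 0.00917). It was also above 1 without control replicate 2 (3.12), knockdown replicate 1 (2.03) or knockdown replicate 2 (1.88), where the regions compared also changed.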

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

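Apart from the comparison of knockdown replicate 1 with control replicate 2, the gene list counts for other splits of the libraries and the photoreceptor count with equal lists, the alternatives were chosen before the data were examined. Knockdown-only regions stayed within 1.5 times of 2555 except with equal lists (791), in the comparison of knockdown replicate 1 with control replicate 2 (3997) and without knockdown replicate 1 (8281) or control replicate 2 (6749), with a range of 2738 to 8281 over the libraries left out. Control-only regions were 9 with a −log10 q of at least 3, 210 with equal lists, 3980 in the comparison of control replicate 2 with knockdown replicate 1, and 90 to 1944 with single libraries left out, where control replicates 1 and 2 (1944 and 1926) and knockdown replicates 1 and 2 (90 and 142) each moved it. Knockdown-only gene ends were 320 with equal lists and 900 to 3543 with libraries left out (the highest without control replicate 2, and 1755 without knockdown replicate 1). Control-only gene ends were 2 with the stricter q, 116 with equal lists, 11 with 3 kb windows and 16 to 266 with libraries left out. The epithelial list stayed past the threshold under every alternative run except equal lists (3 members), with 7 members under the stricter q (odds ratio 6.17 instead of 22.2, 5 of the 13 shared) and 13 to 16 members when libraries were left out (odds ratio 5.69 without control replicate 2). Among genes held by exactly 2 libraries, the adjusted p of this list was 0.00854 instead of 6.22e-09 (Fisher's exact test). The number of lists passing was 2 over loci (sprouting added), 0 with equal lists, and 1 to 2 with libraries left out, where the leukocyte list passed as control-only without control replicate 2. The co-detection ratios lost their call in 1 alternative each, same-group over crossed at 2.48 with the stricter q and same-group over same-number at 0.899 with equal lists. The gene-end odds ratio was 0.850 with the stricter q, 0.474 with equal lists, 1.15 with 50% coverage, and 0.908 to 3.12 with libraries left out, where the set compared also changes. Where a library was left out, the rule itself moved the counts, since the shortened group then needs a peak in only 1 library. The cause of the other moves was not tested, other than the list lengths that the alternatives set. Read depth, unknown here, limits what an absent peak shows.

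The libraries of both groups are numbered 1 and 2, and no label says that a number marks a shared litter or day. With the replicate number as a replicate block, the ratio of peak numbers was 1.62 instead of 1.58, and the region counts were 2555 and 40 by construction, since the rule already asks for the difference in both numbers. Over all regions, the difference between control replicates correlated with that between knockdown replicates at r = 0.0315, which is not negative, and no block of crossed numbers was fitted. Motif alternatives were not run, for lack of sequence.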

Other observations

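The photoreceptor count with equal lists, the use of the equal lists to test list length, and the tests of the added lists between control replicate 2 and knockdown replicate 1 were chosen after seeing the data, and the 4 added gene lists were chosen after seeing the data but before their own values. Outside the fixed lists, further epithelial genes also held knockdown-only gene ends. Of 45 such genes, 9 were knockdown-only, among them the junction gene F11r, the tricellular junction gene Ildr1, the integrin Itgb4 and the claudins Cldn6 and Cldn9, which are neighbours and lie within 1 kb of the same peak. Among the genes with the most knockdown-only regions in their gene body and 10 kb flanks were Cmip with 5 and Arhgap26, Frmd4a, Itgb3 and Prkce with 4 each. These counts were not adjusted for gene length. Cmip, Arhgap26, Frmd4a and Prkce span 204, 775, 596 and 490 kb, and control replicate 2 held 5, 7, 4 and 4 peaks there. Itgb3, an integrin of angiogenic endothelium, spans 62.5 kb and held 0 and 1 peaks in the controls against 4 and 6 in the knockdown libraries. Cdh1, Eps8l2, Gfm1, Myt1l, Rps6ka1 and Stimate had 3 such regions each and 0 peaks in either control. On the Y chromosome, outside the comparisons, the lists held 22, 3, 22 and 13 peaks for control 1, control 2, knockdown 1 and knockdown 2.

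The first pattern is the presence of listed gene-end peaks at epithelial genes in the knockdown libraries and mostly not in the controls. That knockdown-only peaks would reach epithelial genes outside the list was predicted and seen (Fisher's exact test on the added list, odds ratio 6.69, p = 6.80e-05). Shorter control lists as the whole cause are argued against by control replicate 2 and knockdown replicate 1, whose lists are about equally long. Of further epithelial genes outside the list, 11 were held only by the knockdown and 1 only by the control library. Of other genes held by only 1 of these 2 libraries, 55.1% were in the knockdown library (exact binomial test, p = 0.0162, with Cldn6 and Cldn9 counted as 2). Of the 11, 9 are the knockdown-only genes of the added list, so this test and the Fisher's exact test on that list are not separate evidence. Lower sensitivity of the control libraries stays open, since equal length does not make 2 lists equally sensitive. The peaks of knockdown replicate 1 covered 7079 kb and those of control replicate 2 covered 5669 kb. With the 7608 strongest peaks of each library, 3 members of the fixed list were knockdown-only and the list did not pass (odds ratio 6.91, adjusted p = 0.549, Fisher's exact test). That setting cannot decide whether sensitivity caused the pattern. It drops the lower-ranked peaks of the knockdown libraries whatever the cause, and keeps the whole list of control replicate 1. Stray cells of surface epithelium in the knockdown sorts stay open: Krt5, Krt14 and Trp63 held 0 peaks in each library, but 1 of 19 surface epithelium genes, Perp, was knockdown-only, with an upper 95% exact bound of 26.0% that does not fall below the 20.3% set in advance, 0.5 of the epithelial list's 40.6%. Release of genes that Zeb1 represses in endothelial cells is the explanation that the design names, and remains a hypothesis, since neither binding sites nor expression were measured here.

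The second pattern is the photoreceptor signal in the replicate 2 libraries of both genotypes. Longer lists in replicate 2 as the whole cause are argued against by the same 2 libraries: of further photoreceptor genes outside the list, 10 were held only by control replicate 2 and 1 only by knockdown replicate 1, where 55.5% of other such genes were in the knockdown library (exact binomial test, p = 0.00353). A part of list length in the pattern stays open. With the 7608 strongest peaks of each library, 1 of 28 members of the fixed list had the pattern (p = 0.308, Fisher's exact test). That setting cannot decide it. It drops the lower-ranked peaks of the replicate 2 libraries whatever the cause, and keeps the whole list of control replicate 1. More photoreceptor chromatin in the replicate 2 sorts, as from stray rods that an endothelial sort is meant to remove, is a candidate explanation: of 30 further photoreceptor genes, 5 were held by both replicate 2 libraries and neither replicate 1 library (Fisher's exact test, odds ratio 6.55, p = 0.00262). These 5 are among the 10 held only by control replicate 2, so the 2 tests are not separate evidence. No biological explanation was tested, as the design gives none for the replicate number.

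The third pattern is the excess of 2555 knockdown-only over 40 control-only regions, a ratio of 63.9. Unequal list lengths stay open. With the 7608 strongest peaks of each library the ratio was 3.77 (791 and 210 regions). Control replicate 1 then keeps its whole list, down to its lowest-ranked peaks, and the others keep only their top-ranked ones. The ratio at that setting therefore does not decide the question. Without control replicate 1, the counts were 2738 and 1944. A model with library sensitivity and no group effect gave a ratio of 15.7, below the bound set in advance. It expected 1897 knockdown-only and 121 control-only regions, against the 2555 and 40 seen. The model fitted poorly, since it expected 398 regions in control replicate 1 alone where 1884 were seen, so it cannot decide the question. How much of the excess is due to genotype therefore stays open.

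Of the other lists added after seeing the data, fibroblast and stromal genes had 0 of 20 knockdown-only gene ends, with a gene-end peak in 0, 0, 0 and 1 members over the libraries, and further photoreceptor genes had 1 of 30 (Tulp1).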
